A study of Mus musculus with 3 samples.

How the data were processed

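RNA immunoprecipitation sequencing (RIP-seq) recovers the RNAs that are bound to a protein by pulling that protein down with an antibody and sequencing what comes with it. Here the cells were murine BMDCs (bone marrow-derived dendritic cells), and the protein was YTHDF1, a cytoplasmic reader of N6-methyladenosine (m6A) in RNA. The labels describe 2 YTHDF1 RIP samples and 1 input sample of lysate that was not immunoprecipitated. Per the labels' protocols, ribosomal RNA was depleted before paired-end library preparation, and the named kit is not labelled as a directional one. The title of the input calls it an input of meRIP, an assay for m6A, so the labels leave open whether it was made for this YTHDF1 RIP alone.

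The 1 file used holds a list of peaks for the whole series, as 6 columns with no header. Per the submitters' processing notes, Trimmomatic, Bowtie2 and STAR were used and the genome build was GRCm39. Versions, the peak caller, its thresholds, any filter on peaks and the samples it was run on are not given in the sources used here. The deposited start and end of each peak are positions in bases. The deposited score of each peak was 0 in all 6122 cases, so it ranked nothing. The peak names hold the words merge and all6, which may mean a merge of 6 items. The series has 3 samples here, so the list may hold peaks of other libraries too. Each peak has a strand, whose origin (reads, annotation or merging) is not stated in the sources used here. The list carries no read count, no enrichment, no p-value and no sample name. The 2 RIP samples therefore could not be set against each other or against the input, sequencing depth is unknown, and no value below has an error between replicates. Intervals and p-values describe the peaks of this 1 list and cover counting error or the stated permutation only.

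Peaks could not be assigned to nuclear genes. The gene table used here is of another build, GRCm38.p6, and the coordinates were tested against it. At the listed positions, 59.9% of peak midpoints on the autosomes and X fell inside a protein-coding gene of the table, against 47.7% and 48.6% after moving all peaks by 1 Mb up or down. In windows of 20 Mb with at least 15 peaks, moving the peaks by up to 600 kb in steps of 5 kb raised the median share from 61.0% to 85.7%, and in 7 of 122 windows no shift was better than 0. The best of as many shifts around a point 5 Mb up or down, which measures what picking the best shift gives by chance, was 60.4% and 61.1%. In addition, 7 peaks lay beyond the last gene of the table, 6 on chromosome 8 and 1 on chromosome 13. The table was accordingly used for the names, chromosomes and spans of genes, and no position was converted between builds. The exception was the mitochondrial genome, whose mouse reference sequence is taken to be the same record in both builds.

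All 6 results planned before the data were examined needed genes, transcript features, genome sequence or a peak score, and none was run. They were the genes with an exonic peak, the placement over untranslated and coding sequence, the density of the m6A consensus, the lysosomal proteases, the other gene lists and the peak strength. The 23 gene lists fixed in advance hold 434 different genes, of which 432 were found in the table by symbol or synonym. They were not tested against the peaks, which includes all lists of cell type markers. The rule for named genes asked for every lysosomal protease, and the strongest members of the other lists. Of these, only the lysosomal proteases are named, with their chromosomes. The mitochondrial peak and its genes ND5 and ND6 fall outside the rule and were chosen after their values were seen. The other runs and peaks named by position were chosen by a rule set after the file was opened, namely the 5 runs with the most peaks and the widest peak.

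What was computed from the deposited positions was as follows, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Peaks per 100 protein-coding genes were taken per chromosome. Each peak name ends in a number. Numbers increased along every chromosome without exception, so a missing number marks a place in the order that the list does not hold. The share of numbers present was taken between the first and last listed number of each chromosome, with 95% Wilson intervals. The X chromosome and the 19 autosomes were compared by permuting whole blocks of 50 consecutive numbers 10000 times, two-sided. Pairs of consecutive numbers were compared with 1000 random placements within each chromosome. The strands of neighbouring peaks were compared with 10000 permutations of strand within chromosomes. Neighbouring peaks of 1 strand no more than 10 kb apart were joined into runs. The block permutation and the count of same-strand pairs were checked on simulated data. With the share of numbers present on X set to 0.7 of that on the autosomes, the mean ratio recovered over 20 simulated lists was 0.712 and 20 lists had a permutation p under 0.05, against 0 of 20 lists with no difference. Numbers in these lists were drawn independently at the same rate on all autosomes. The simulated lists thus lacked the clustering and the spread between chromosomes of the real list, and do not show that its p is correct. A same-strand share set to 90% was recovered as 90.2%. This checks the counting of pairs only, since the permutation of strands was not run on simulated data. The alternatives tried were other gene counts, block lengths, distances and subsets of peaks, all chosen after the file was opened.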

Results

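RIP-seq of YTHDF1 in BMDCs was carried out to ask whether transcripts that encode lysosomal proteases and carry m6A are recognised by this reader protein. The samples were 2 YTHDF1 immunoprecipitates and 1 input, and the result analysed here was 1 list of 6122 peaks on GRCm39 that does not separate the samples. The peak names hold the words merge and all6, which may mean a merge of 6 items that the sources used here do not identify. The peaks are therefore not known to come from these 3 samples alone. The list covered 38.1 Mb and held peaks on all 19 autosomes (5997 peaks), the X chromosome (122 peaks), the mitochondrial genome (1 peak) and 2 unplaced scaffolds (2 peaks), and 0 peaks on the Y chromosome. It gave 3140 peaks (51.3%, 95% Wilson interval 50 to 52.5%) on the plus strand and 2982 (48.7%) on the minus strand. No separate values of the input were analysed, so no background level stands beside the peaks.

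The lysosomal proteases are the enzymes that degrade endocytosed protein, and in dendritic cells they act on antigen. The list fixed in advance held 20 of them on 11 chromosomes. Chromosome 7 carried 421 peaks and holds 5 of these genes, namely Ctsc (cathepsin C), Ctsd (cathepsin D), Tpp1, Prcp and Napsa. Chromosome 3 carries Ctsk, Ctso and Ctss (cathepsin S, which degrades the invariant chain of MHC class II) and had 292 peaks. Chromosome 2 carries Ctsa, Ctsz and Dpp7 and had 501 peaks, and chromosome 19 carries Ctsf and Ctsw and had 222. The remaining members were single on their chromosomes. These were Ctsb on 14, Ctse on 1, Ctsh on 9, Ctsl on 13, Lgmn (legumain) on 12, Scpep1 on 11 and Cpq on 15. Whether any of these 20 genes held a peak was not analysed here, because the peaks were not assigned to nuclear genes, and a count of peaks per chromosome says nothing about a single gene on it.

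The single mitochondrial peak covered bases 12653 to 14070 of the mitochondrial genome, 1418 bases listed on the plus strand. Its positions held 913 bases (50.1%) of ND5 and all 519 bases (100%) of ND6. These are neighbouring genes for subunits of respiratory complex I and are transcribed from opposite strands. Overlap was counted without regard to strand, and the listed plus strand cannot match both genes. Full overlap with ND6 therefore does not show that ND6 transcripts were recovered. The highest position of the peak was also the highest position of ND6, with a difference of 0 bases. These gene names rest on the mitochondrial sequence being shared by both builds. No other mitochondrial gene, including the ribosomal RNAs, overlapped a listed peak.

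Among X and the 19 autosomes, X carried the fewest peaks for its genes. It had 12.6 peaks per 100 protein-coding genes (122 peaks, 966 genes), and the autosomes had 29.0 together, with a mean of 29.6 ± 3.9 (SD over 19 autosomes). The ratio of X to autosomes was 0.44 (95% interval from counting error 0.36 to 0.52). This interval treats peaks as independent and leaves out the spread between autosomes, so it is too narrow. Chromosomes 16, 15 and 10 had the most, at 35.5, 35.1 and 34.7 peaks per 100 genes, and chromosome 7 had the fewest of the autosomes, at 20.7. Chromosome 7 is rich in genes for olfactory and vomeronasal receptors. Without the 1478 chemosensory receptor genes, chromosome 7 had 26.1 peaks per 100 genes, chromosome 14 was the lowest autosome at 23.6, and X had 12.7 against 31.2 on the autosomes. X ranked lowest of 20 chromosomes, and an exact rank among 20 cannot give a one-sided p under 0.05.

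The numbers in the peak names ran from 19 to 57466 in genome order, so the list held 10.7% of the numbers up to the highest. What the other 51344 numbers stood for is not stated in the sources used here. The share of numbers present was 7.54% on X (95% Wilson interval 6.34 to 8.94%) and 10.78% on the autosomes (10.53 to 11.04%), a ratio of 0.70 (block permutation, two-sided, p = 0.0008). Among autosomes the share ran from 8.92% on chromosome 18 to 12.3% on chromosome 10, a spread larger than that of permuted blocks (block permutation p = 0.0097). The p for X leaves out this spread between chromosomes and is therefore too small. Set against single autosomes (mean 10.72% ± 1.14, SD, n = 19), X was the lowest of 20, for which the exact one-sided rank p is 0.05, the smallest possible. X had fewer numbers per protein-coding gene, 1.65 against 2.67 on the autosomes together, but chromosome 7 had nearly as few, at 1.69. Without chemosensory receptor genes the values were 1.66 on X, 2.88 on the autosomes and 2.13 on chromosome 7. Numbers per gene multiplied by the share of numbers present give nearly the peaks per gene. Both values therefore split the low peak count on X into parts and are not separate results.

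**Figure D1:**
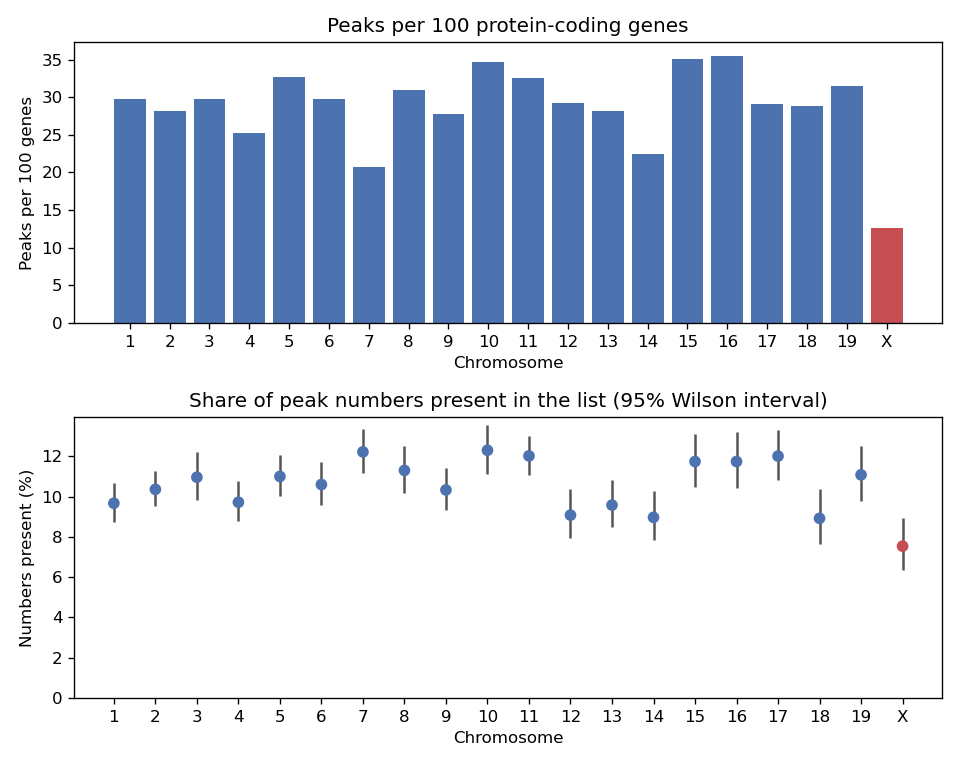
Upper panel, peaks per 100 protein-coding genes (bars) for each chromosome; lower panel, the share of peak numbers present in the list in percent (points) with 95% Wilson intervals (lines). X, in red, is lowest in both panels, at 12.6 peaks per 100 genes and 7.54%. The share in the lower panel is a factor of the peaks per gene in the upper panel.

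Listed peaks that lay close together mostly had the same strand. How a strand was given to each peak (from reads, gene annotation or merging) is not stated, so these values describe listed strands only. Of 1814 pairs of neighbouring peaks within 10 kb, 1695 (93.4%, 95% Wilson interval 92.2 to 94.5%) shared a strand and 119 did not. Permuted strands gave 50.2% on average and 54.8% at most (p = 0.0001, the smallest that 10000 permutations can give). The permutation takes the strands of neighbouring peaks as independent. Pieces of the same transcript or region would share a strand however it was given, so a low p was likely in advance. It says only that listed strands are not independent of position. The share was 95.3% below 500 bases, 79.3% from 10 to 50 kb, 62.4% from 50 to 100 kb and 48.5% (44.7 to 52.4%) beyond 1 Mb. Pairs with consecutive numbers occurred 1069 times, against 656 on average and 723 at most in random placements, a ratio of 1.63 (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Such pairs lay a median of 635 bases apart. Random placement leaves out any clustering along a chromosome, so this p says only that listed numbers cluster.

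**Figure D2:**
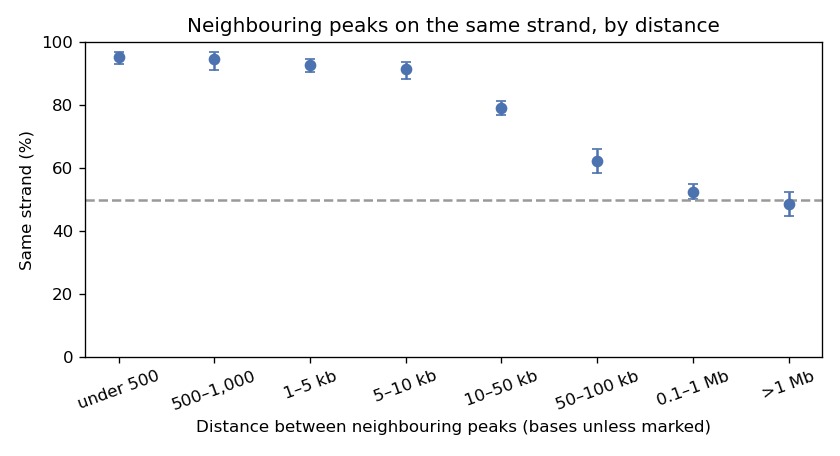
Share of neighbouring pairs of peaks on the same strand in percent (points, with 95% Wilson intervals) by the distance between them; the dashed line marks equal numbers of same and opposite strands. The share falls from 95.3% below 500 bases to 48.5% beyond 1 Mb.

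Joining same-strand neighbours gave 4427 runs, of which 1027 held 2 or more peaks and together 2722 peaks (44.5%). The number of such runs depends on the distance allowed, and was 558 with 1000 bases. The 5 runs with the most peaks lay in 5 different chromosomes. The run with the most peaks held 19 on the minus strand of chromosome 2, from 44921423 to 44999945, a span of 78.5 kb of which peaks covered 32626 bases. Runs of 13 peaks lay on the plus strand of chromosome 19 from 8966692 to 8996432, on the minus strand of chromosome 5 from 17987384 to 18037962, and on the minus strand of chromosome 10 from 127360510 to 127429561. A run of 11 peaks lay on the minus strand of chromosome 15 from 76055434 to 76075431. The genes at these positions are not named here.

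Peak widths ran from 200 to 49923 bases with a median of 1444 and quartiles of 427 and 7461 bases. Counted in bins that double in width, the distribution had a narrow and a broad part. From 200 to 400 bases there were 1408 peaks, from 1600 to 3200 bases 585, and from 3200 to 6400 bases again more, 702. Peaks wider than 10 kb made up 20.1% of the list (1232 peaks, 95% Wilson interval 19.1 to 21.1%) and 73.6% of the length it covered. The widest peak lay on the minus strand of chromosome 18, from 84038128 to 84088050. Each peak has 1 start and 1 end, so bases within a broad peak are not resolved into exons and introns. For scale, the median span of a protein-coding gene with its introns was 17146 bases in the gene table.

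Peaks were broader on chromosomes with longer genes. Over the 20 chromosomes, the median peak width followed the median span of protein-coding genes, with Pearson's r = 0.72 (permutation p = 0.0012, adjusted 0.0024) and Spearman's rho = 0.65 (permutation p = 0.003, adjusted 0.003 over these 2 coefficients). Chromosome 18 had the longest genes, with a median span of 33127 bases, and the broadest peaks, with a median of 3265 bases. Without chromosomes 18 and 1, whose gene spans were farthest from the median, r was 0.64 (permutation p = 0.004). This relation is across chromosomes of 1 list, which are not independent samples. Peaks that stood alone were broader than those in runs, with medians of 2299 and 942 bases (permutation p = 0.0002, two-sided, the smallest that its resamples can give). This p treats peaks of the same run as independent and is therefore too small. Width and membership in a run are also linked by construction, since a region listed in pieces gives a run of narrower peaks.

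**Figure D3:**
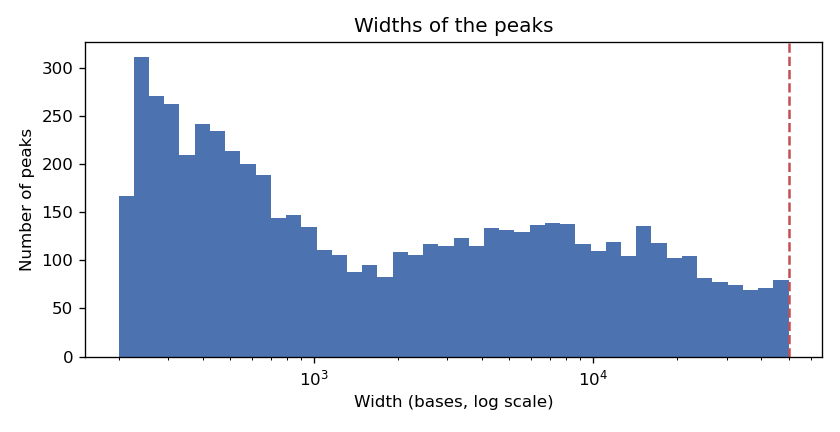
Number of peaks by width in bases on a log axis; the dashed line marks 50 kb. In bins of equal size on the log axis, the counts dip between the narrow and the broad part. They stop short of 50 kb, with 49923 bases as the largest width.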

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

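All alternatives here were chosen after the data were examined, since none of the 6 results fixed beforehand could be computed, and the settings fixed for them were therefore not run. X over autosomes in peaks per gene stayed between 0.38 (all genes of the table) and 0.44 under 5 alternatives, and the share of numbers present stayed between 0.66 (outer ends of each chromosome left out) and 0.70 of the autosomal share under 4, with block permutation p from 0.0001 to 0.0025, which leave out the spread between chromosomes. The same-strand share of close neighbours stayed between 87.8% (within 50000 bases) and 95.3%, with permutation p = 0.001 in all 5 alternatives, the smallest that 1000 permutations can give. These permutations also take neighbouring strands as independent. The excess of nearby numbers was 1.5 for numbers that differ by 1 or 2 and 1.23 for numbers exactly 5 apart, both with permutation p = 0.003, the smallest that the 300 placements drawn for them can give. These placements leave out clustering as well. Spearman's rho of peak width with gene span stayed between 0.65 and 0.71 under 3 alternatives. Runs of 2 or more peaks fell from 1027 to 558 when neighbours had to lie within 1000 bases, because fewer pairs then qualify, and numbered 856 and 1303 with 5000 and 50000 bases. The share wider than 10 kb was 20.9% with equal weight per chromosome, and 25.8% when only the widest peak of each run was counted, a choice that raises the share by its construction. No replicate could be left out, since the list does not separate the samples. No paired analysis was possible because the list carries no sample or replicate number. The depth behind the peaks is unknown, as no read count was analysed.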

Other observations

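Of the tests below, the one without chemosensory receptor genes and the shift of the minus-strand peaks were specified before their values were seen, and the others after.

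The design holds no group that bears on the low peak count on X, so no difference between groups was tested as its explanation. Leaving out chemosensory receptor genes gave 0.41 of the autosomal peaks per gene, but this could not have raised the ratio, because these genes make up 0.72% of the genes on X and 7.12% on the autosomes. The bound set for that test was therefore uninformative, and other differences in gene content stay open. Numbers per protein-coding gene on X were 0.62 of the autosomal value (0.58 without chemosensory receptor genes), and the share of numbers present was 0.70 of it. Multiplied together, numbers per gene and this share give nearly the peaks per gene, so they divide the low count and do not explain it. The share is open because autosomes differ among themselves. For numbers per gene, chromosome 7 came close to X (1.69 against 1.65), though less so without chemosensory receptor genes (2.13 against 1.66). What the numbers stood for is not stated, so neither value measures transcripts from X. Fewer or more weakly recovered transcripts from X, or a threshold that favours abundant transcripts, are hypotheses that were not tested. Read counts would be needed to test them.

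No peak was wider than 50 kb, although the counts were still well above 0 just below that point. There were 641 peaks from 10 to 20 kb, 291 from 20 to 30 kb, 168 from 30 to 40 kb, 132 from 40 to 50 kb and 0 beyond. Continuing at the ratio of 0.79 per 10 kb would give 484 peaks beyond 50 kb, and 204 at the lower 95% limit of that ratio. An upper limit on width during processing is a candidate explanation. If there was one, the broadest regions are absent as single peaks, and whether they were dropped, cut or split is not known. Of the same-strand runs of 2 or more peaks, 58 spanned over 50 kb. Runs join peaks across gaps of up to 10 kb, so a long span does not show that a broad region was split.

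No peak overlapped another, on either strand. The smallest distance was 140 bases between peaks of the same strand and 154 bases between peaks of opposite strands. Moving the minus-strand peaks along their chromosomes gave 48.0 overlaps with plus-strand peaks on average (22 to 89 in 1000 shifts), which argues against peaks too sparse to meet. The shift also undid the local arrangement of strands, in which 93.4% of neighbours within 10 kb shared a strand. It therefore cannot tell a processing step from an arrangement in which peaks of opposite strands seldom lie in the same place. Merging or removal of intervals without regard to strand may also have produced the lack of overlap, and these cannot be separated here. If intervals were merged, the strand of a peak may be that of a merged region, which bears on the mitochondrial peak that covers ND5 and ND6.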
